A study of Tagetes erecta with 24 samples.

How the data were processed

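The data were the values that the authors deposited for 24 libraries of marigold petals, and the reads were not used. The labels describe RNA taken with a column kit, checked with a NanoDrop and a Bioanalyzer (integrity number over 9), and made into stranded libraries with the NEBNext Ultra Directional kit. The processing notes of the series name FastQC, Cufflinks and Cuffdiff without versions, and the aligner and the assembler are not given in the sources used here. The FPKM values were computed by the authors as fragments per kilobase of unigene scaled to the number of fragments in the library, and were rescaled between libraries before they were deposited by a factor that the sources do not give. A table of unigenes deposited by the authors gives each unigene's length, open reading frame, strand and best protein match. No reference genome came with this series, so no position in a genome was given to any unigene.

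The files were checked before use. Each held 49217 unigenes in the same order, and no pair of libraries was identical. Raw counts were not used here, and depth was estimated from the spacing of low FPKM values times length in unigenes of 600 to 2000 bases: a value counted as on a step when it lay within 0.05 of a whole number of fragments, up to 3 fragments. Replicates 2 and 3 had such steps and replicate 1 did not, so no depth is given for the 8 libraries of replicate 1. Values at 0 cannot be told from values under 1 fragment. Sums of FPKM ranged from 874911 in V-01M_II-3 to 3958828 in V-01M_III-1, which is why shares are given of FPKM times length.

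Samples were grouped by line and stage from the labels. The 14 comparisons, the gene lists, the tests, the limits and the alternatives were set before the data were examined, except for those named as added. The comparisons were V-01M against V-01 at each of the 4 stages, their average over stages, the successive stages and stage IV against stage I in each line, and the interaction of line with stage IV against stage I. Unigenes called in 1 direction at all 4 stages were counted as well. Whether replicate numbers pair the samples was tested with correlations of residuals in 12 comparisons: none had all 3 correlations over 0.1 (range −0.13 to 0.37), so no pairing was used. The highest, 0.27 and 0.37, belonged to replicates 1 and 2 of the line comparison at stage I, where replicate 3 gave 0.

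Unigenes were kept when at least 3 libraries had 1 FPKM or more, which left 42423. Values were taken as log2(FPKM + 1). A linear model with 8 groups over all 24 libraries was fitted with limma 3.58.1 in R 4.3.3, with a trended and robust prior. Unigenes were called at an adjusted p under 0.05 (Benjamini and Hochberg, over all unigenes of a comparison) and a log2 difference of at least 1. Tools for raw counts were not used, because the values are not counts. Standard errors are those of the moderated fit, and 95% intervals use its degrees of freedom.

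Gene lists were made from keywords in the protein matches, in 11 lists: carotenoid biosynthesis, isoprenoid precursors, carotenoid cleavage and storage, phenylpropanoid and flavonoid, photosynthesis, cell proliferation, cell wall and expansion, transcription factors, stress and senescence, specialised metabolism, and other tissues and organisms. Of these 9 were tested with camera (inter-gene correlation 0.01) in 4 comparisons, with adjustment over the 36 tests, and the cleavage and storage list and the other tissues list were only counted. Keywords brought in some neighbours: histone methyltransferases among histones, P450 reductases among P450 enzymes, dolichyl glycosyltransferases among glycosyltransferases, proteinase inhibitors among cysteine proteinases, and plant RNA polymerases and spore coat proteins among viral proteins. No unigene matched the keyword for the ORANGE protein, though 3 held a peptide motif set for it and were not listed as ORANGE. Carotenoid unigenes to name were the highest of each enzyme family and other called members with a mean of at least 5 FPKM. For other lists up to 3 called members with the largest differences were named per comparison, with at least 5 FPKM in the higher group. Among all unigenes without overlap of replicates, the 10 largest differences up and down were taken for the average and 3 up and down for each stage.

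The tests were checked on simulated data, drawn from the group means and the spread of each unigene with no difference between the lines. Log2 changes of 1, 2, 3 and 4, up or down, were added to 50 unigenes each at stage IV of V-01M, and 18%, 62%, 82% and 84% were called, with 0 of the wrong sign. Of 140 calls 123 were of these unigenes, 11 were false and 6 were in the isoprenoid list, to which a shift of 1 was added at all stages of V-01M. That shift was called by camera. The simulated unigenes vary independently of each other, so the simulation does not test false list calls. Each unigene was given 1 normal spread for all groups. The simulation therefore does not test spreads that differ between groups or single outlying libraries. The changes were added only to unigenes with a mean level of at least 2 in log2 units, so the shares called do not hold for lower ones.

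Alternatives set beforehand were a pseudocount of 0.1 or 5, no filter or a filter on a mean of 5 FPKM, median-of-ratios or quantile scaling, a replicate term, a fit with the compared groups only, a prior without trend, each library left out in turn, other limits, and an estimated inter-gene correlation or fry for lists. Added after values were seen were replicates 2 and 3 only, fits without virus unigenes, fabavirus load as a covariate, sums over sibling unigenes, the test of opposite siblings against matched draws, and fits without unigenes seen in 1 group only. Virus unigenes were classed by matches to fabavirus and cucumovirus proteins after their share was seen. Siblings were aligned with BLAST+ 2.17.0, taking identity of at least 90% over 100 bases as near-identical. Random draws of 10000 sets matched on number of siblings and mean level gave the chance of opposite siblings. Exact permutation tests ran over all labellings within stages (160000) or groupings of the 12 libraries of a line (220). For single comparisons all 10 splits of 6 libraries were refitted, and for the average and the interaction 100 draws of line labels. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, draws and plots.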

Results

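Petals of marigold (Tagetes erecta) were profiled by RNA sequencing in line V-01 and in V-01M, described in the labels as its natural mutant, at petal development stages I, II, III and IV. Each line and stage had 3 libraries (n = 3 in each of 8 groups, 24 libraries in all), and the labels do not say whether the libraries of a group came from separate plants. The labels give the petal colours in opposite ways: one text makes V-01 the yellow line and V-01M the orange one, and another makes V-01 orange and V-01M yellow. The lines are therefore named here without a colour. Plants were kept in a climate chamber at 22 °C and 70% relative humidity with 16 h of light and 8 h of dark.

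Expression was given in fragments per kilobase of unigene, scaled to library size (FPKM), for 49217 unigenes of an assembly made without a reference genome, so positions in a genome are not known. Unigenes had a median length of 716 bases (224 to 13450), and 33851 of them (68.8%) carried a protein match. Names such as TR15738|c0_g1 end in a unigene number (_g1), and all that stands before it (TR15738|c0) is called the component here. Unigenes of 1 component are called siblings, so unigenes that differ in the part after the bar and before the unigene number are not. After a filter on low values, 42423 unigenes were tested, of which 29072 carried a protein match.

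Depth was read from the steps between low FPKM values. In the 16 libraries of replicates 2 and 3, 98.1% to 99.8% of low values fell on multiples of 1 fragment, and in the 8 libraries of replicate 1 11% to 33.4% did. Among these 16, the steps implied 4.32 fragments for each FPKM and kb in V-01_IV-2, the lowest, and 23.94 in V-01_I-2, the highest, with a median of 12.2. In a unigene of 1 kb, 1 fragment stood for 0.0418 to 0.2312 FPKM. V-01_IV-2 also had the fewest unigenes at 1 FPKM or more (32218, against up to 38642 in V-01_II-1) and 11306 unigenes at 0. Replicate correlations within the groups were 0.824 to 0.940, and no pair of libraries was identical. On a principal component plot the first component held 34.6% of the variance and the second 14%. Stages I and II lay together on the first (−117.4 to −31.3), followed by stage III (−12.8 to 74.4) and stage IV (115.2 to 184.3). V-01_I-2, at −31.3 and 89.7 on the first and second components, lay apart from V-01_I-1 (−111.5 and 29.4) and V-01_I-3 (−117.4 and 17.9) and nearer to V-01M_I-2 (−37.4 and 84.9).

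Some carotenoid enzyme transcripts rose in petals of both lines between stage I and stage IV, with 3 of 13 unigenes called up in V-01 and 4 in V-01M. Lycopene epsilon cyclase (TR11756|c0_g1), which opens the branch to alpha-carotene and lutein, rose from 20.8 ± 2.48 to 67.1 ± 21.6 FPKM in V-01 (mean ± SD here and below; log2 1.59, SE 0.28, adjusted p = 0.000262) and from 14.5 ± 2.01 to 60 ± 17 FPKM in V-01M (log2 1.94, SE 0.28, adjusted p = 5.19e-05). A phytoene synthase unigene (TR27238|c0_g1), for the enzyme of the first committed step, went from 0.0105 ± 0.0182 to 9.91 ± 5.73 FPKM in V-01 and from 0.0106 ± 0.0183 to 17.5 ± 6.22 FPKM in V-01M (log2 3.24 and 4.14, SE 0.52). It was chosen after its values were seen, because its mean over all libraries was under the 5 FPKM set for naming a unigene. Phytoene desaturase (TR15738|c0_g1) rose from 23.5 ± 4.86 to 48.9 ± 8.1 FPKM in V-01 and from 21.3 ± 0.54 to 46 ± 5.87 FPKM in V-01M (log2 1.03 and 1.07, SE 0.26, adjusted p = 0.00508 and 0.00495). Zeta-carotene desaturase (TR6555|c0_g1) rose in V-01M from 17.6 ± 1.27 to 41.3 ± 3.74 FPKM (log2 1.19, SE 0.31, adjusted p = 0.00724) and was not called in V-01 (log2 0.39), and its difference between the lines was not called either (log2 0.80, adjusted p = 0.673).

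The desaturase calls of TR15738|c0_g1 rested on log2 changes close to the limit of 1. They were 0.89 and 0.90 after quantile normalization, 0.94 and 0.98 with replicates 2 and 3 only, and 0.92 and 0.95 with a pseudocount of 5, in V-01 and V-01M in turn. The V-01 value was 0.89 without V-01_I-1 and 0.90 without V-01_IV-2, and the V-01M value was 0.98 without V-01M_IV-1 and 0.99 after median-of-ratios scaling. Beta-carotene hydroxylase (TR3323|c0_g1) was not called over the full course (log2 1.57 in V-01 and 1.54 in V-01M, SE 0.70), but passed the limits without V-01_I-2 (2.28) and without V-01M_I-2 (2.24). The most abundant phytoene synthase unigene (TR27514|c0_g1) was not called in either line (log2 0.23 and 1.05), and the V-01M change was called without V-01M_I-2 (1.35) or V-01M_IV-3 (1.28). Violaxanthin de-epoxidase (TR3622|c0_g1) was at a log2 change of −0.97 in V-01 and was called without V-01_IV-2 (−1.44) and with a pseudocount of 0.1 (−1.17), and phytoene synthase TR27514|c1_g1 was at −0.79 and not called. In V-01M they were at −0.42 and 0.46 and not called. Lycopene beta cyclase (TR13418|c0_g1), carotenoid isomerase (TR5914|c0_g1) and zeaxanthin epoxidase (TR9258|c0_g1) were not called, with log2 changes of 0.42, 0.23 and −0.03 in V-01 and 0.70, 0.52 and 0.50 in V-01M.

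In V-01 most of the carotenoid calls between successive stages came with stage III. From stage II to III beta-carotene hydroxylase rose from 25.5 ± 8.43 to 227 ± 168 FPKM (log2 2.77, SE 0.70, adjusted p = 0.0155), zeta-carotene desaturase from 24.3 ± 3.2 to 68.6 ± 35.4 FPKM (log2 1.31, SE 0.31), lycopene epsilon cyclase from 44.1 ± 5.84 to 105 ± 38.3 FPKM (log2 1.17, SE 0.28) and phytoene desaturase from 22.9 ± 3.92 to 52.4 ± 22.7 FPKM (log2 1.07, SE 0.26). Phytoene synthase TR27238|c0_g1 rose in that step from 0.082 ± 0.0791 to 4.12 ± 5.16 FPKM (log2 1.73, SE 0.52, adjusted p = 0.0387). It read 0.4252, 10.02 and 1.915 FPKM in V-01_III-1, V-01_III-2 and V-01_III-3. In these libraries the hydroxylase read 57.66, 228.7 and 394.5 FPKM and zeta-carotene desaturase 30.79, 74.07 and 100.9 FPKM. Epsilon cyclase read 66.62, 103.8 and 143.2 FPKM and phytoene desaturase 27.81, 56.78 and 72.61 FPKM. From stage III to IV of V-01 the hydroxylase fell to 43.9 ± 18.8 FPKM (log2 −2.04, SE 0.70, adjusted p = 0.0475), zeta-carotene desaturase fell to 28.3 ± 5.53 FPKM (log2 −1.11), and phytoene synthase unigenes TR27514|c0_g1 and TR27514|c1_g1 fell from 87.6 ± 41.6 to 30.6 ± 9.5 and from 37.2 ± 13.1 to 10.7 ± 1.79 FPKM. In V-01M the hydroxylase also rose from stage II to III, from 14.3 ± 5.43 to 65 ± 25.6 FPKM, and was not called (log2 2.11, SE 0.70, adjusted p = 0.0822). The steps that were called there were the rise of lycopene epsilon cyclase from stage I to II (log2 1.30, SE 0.28, adjusted p = 0.0452) and of phytoene synthase TR27238|c0_g1 from 0.312 ± 0.0917 FPKM at stage III to 17.5 ± 6.22 FPKM at stage IV (log2 3.76, SE 0.52, adjusted p = 0.000259). Unigenes were named for the successive steps after their values were seen, and differences between the lines in these steps were not tested. For single unigenes in these steps no calls with a library left out are given, so calls that involve stage III of V-01 may rest on 1 library.

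**Figure D1:**
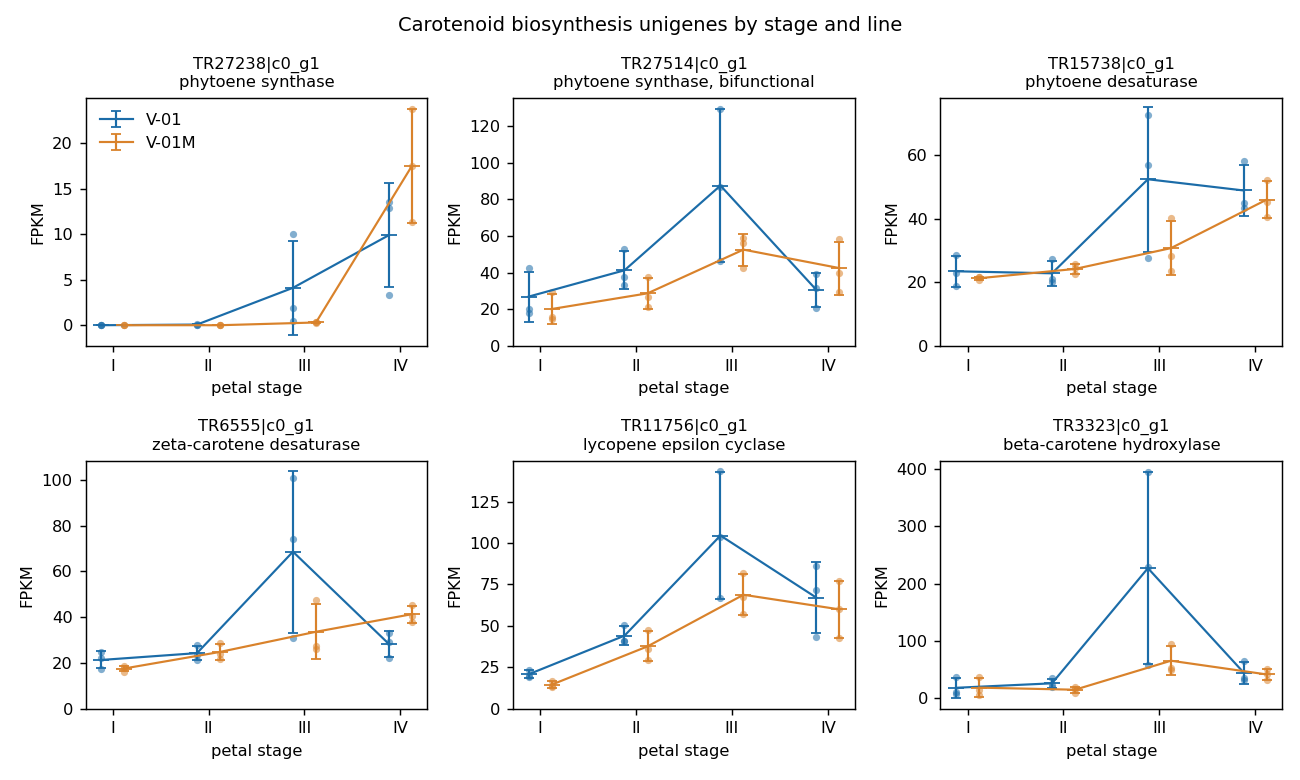
FPKM of 6 carotenoid enzyme unigenes at stages I to IV in V-01 (blue) and V-01M (orange), with 1 point per library and bars of mean ± SD (n = 3). Lycopene epsilon cyclase averaged 105 FPKM at stage III of V-01 and 68.8 FPKM at stage III of V-01M, and beta-carotene hydroxylase 227 and 65 FPKM, without a called difference between the lines.

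Carotenoid enzyme transcripts did not differ between the lines at any stage by the limits used. At stage III all of the 13 carotenoid unigenes but zeaxanthin epoxidase TR9258|c0_g1 (0.01) had lower fitted values in V-01M, with log2 differences down to −1.47. Beta-carotene hydroxylase stood at 65 ± 25.6 FPKM in V-01M and 227 ± 168 FPKM in V-01 (log2 −1.47, SE 0.70, adjusted p = 0.479), and zeta-carotene desaturase at 33.6 ± 11.9 and 68.6 ± 35.4 FPKM (log2 −0.90, SE 0.31, adjusted p = 0.271). Without V-01_III-1 the stage III differences of zeta-carotene desaturase (−1.39) and phytoene desaturase (−1.07) were called. At stage IV phytoene synthase TR27514|c1_g1, chosen after the values were seen, stood at 25.2 ± 7.63 FPKM in V-01M and 10.7 ± 1.79 FPKM in V-01 (log2 1.13, SE 0.31, 95% interval 0.48 to 1.79, adjusted p = 0.11). Of the 13 carotenoid unigenes 0 were called at each stage by limma, with 0, 0, 5 and 1 at an unadjusted p under 0.05 at stages I to IV. Adjusted over the list alone, 1 rose at stage IV and 0 changed at the other stages.

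Some of the largest line differences averaged over the 4 stages sat in unigenes near 0 in 1 line and abundant in the other. TR29645|c0_g1, matched to eukaryotic release factor subunit 1-3 of translation termination, averaged 58.2 ± 12.4, 64.9 ± 11.7, 75.3 ± 8.12 and 79.3 ± 25.5 FPKM at stages I to IV of V-01, 0.278 ± 0.482 at stage I of V-01M, and was listed at 0 at its later stages. Its sibling TR29645|c0_g2 did the reverse, with 46 ± 11.5, 57 ± 6.4, 81.1 ± 18.6 and 87 ± 9.76 FPKM in V-01M and at most 0.295 FPKM on average in V-01. A cellulose synthase subunit 5 pair, TR16972|c0_g1 and TR16972|c0_g2, was exchanged in the same way, at 10.9 to 28.6 FPKM in V-01 and 13.7 to 31.8 FPKM in V-01M. Summed over the siblings neither was called (log2 −0.06 for the release factor and 0.12 for subunit 5). Photosystem II 10 kDa polypeptide (TR11736|c0_g1) was higher in V-01M at each stage, from 267 ± 54.2 against 6.14 ± 1.53 FPKM at stage I to 402 ± 206 against 14 ± 7.37 FPKM at stage IV (log2 4.66, SE 0.27, adjusted p = 9.22e-10).

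Glycosyltransferase 89B1 (TR29833|c0_g2) stood at 8.97 ± 1.75, 7.08 ± 0.346, 16.3 ± 2.79 and 35 ± 1.33 FPKM in V-01M and at 0.907, 0.725, 0.984 and 3.72 ± 0.44 FPKM in V-01 (log2 2.69, SE 0.12, adjusted p = 1.86e-11). Ribosomal protein L7a-2 (TR11255|c0_g2) averaged 306 ± 168, 272 ± 73.5, 223 ± 113 and 73.3 ± 34.1 FPKM in V-01 and was listed at 0 at stages I to III of V-01M. Summed over its component the difference was smaller and still called (log2 −1.43, against −7.25 for the unigene alone). Peroxidase 12 unigenes also parted: TR27389|c1_g1 stood at 8.79 to 41.5 FPKM in V-01M and 0.0315 to 0.129 FPKM in V-01 (log2 4.18, SE 0.22), and TR30329|c0_g3 at 15.5 to 41.3 FPKM in V-01M against at most 0.0742 FPKM, while its sibling TR30329|c0_g2 stood at 6.61 to 30.3 FPKM in V-01 against at most 0.0472 FPKM. Summed over their components these were at 0.56 (TR27389|c1_g1, not called) and 1.32 (TR30329|c0_g3 and TR30329|c0_g2, called). Cellulose synthase subunit 6 (TR31380|c0_g2) stood at 2.52 to 6.33 FPKM in V-01 and at most 0.0417 FPKM in V-01M, and was not called with a pseudocount of 5. Its sibling TR31380|c0_g1 went the other way (log2 1.59), and their sum was not called (−0.87). Unigenes without a protein match parted too, such as TR12725|c0_g2, at 22.7 to 32.6 FPKM in V-01 and listed at 0 in every V-01M group, whose sibling TR12725|c0_g1 went the other way (3.94, sum −0.79, not called), and TR27139|c3_g3, at 25.3 to 95.4 FPKM in V-01M and at most 0.809 FPKM in V-01. Summed over its component TR27139|c3_g3 was at log2 1.65 and called, against 5.6 alone.

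The averaged contrast called 140 unigenes, 73 higher and 67 lower in V-01M, 2 of them of viral origin, and 128 (71 and 57) with replicates 2 and 3 only. Without V-01_IV-2 it called 224. At each of the 4 stages in the same direction 47 were called (25 higher, 22 lower), and 27 with replicates 2 and 3 only. Of the 138 plant unigenes called, 41 (29.7%) had a sibling that went the other way by at least 1 log2 unit, against a highest value of 6 in 10000 random draws of unigenes with like numbers of siblings and like levels. The 41 made up 21 distinct pairs, so most pairs were counted from both sides. The draws took unigenes independently and would seldom count a pair in that way. When FPKM values were summed over each component, 77 of 34422 components were called (42 higher, 35 lower), 12 of them in 1 direction at all 4 stages. Of the 314 specialised metabolism unigenes 1 rose and 1 fell, of 226 cell wall unigenes 3 rose and 2 fell (5 and 2 over the list alone). The specialised metabolism pair were siblings (TR29833|c0_g2 and TR29833|c0_g1), and their sum was called (log2 1.99). Of the 5 cell wall calls 4 were the sibling pairs of cellulose synthase subunits 5 and 6, whose sums were not called. None was called among the 13 carotenoid, 43 isoprenoid, 43 phenylpropanoid, 58 photosynthesis, 112 proliferation, 517 transcription factor and 69 stress unigenes. None was called either among 110 carotenoid cleavage and storage unigenes, of which 103 are GDSL esterases or lipases and 7 are cleavage dioxygenases, and 20 unigenes of other tissues and organisms. Those 9 lists had 1, 3, 7, 5, 4, 55, 1, 20 and 1 unigenes at an unadjusted p under 0.05 in limma, and 0 over the list alone. The photosynthesis list holds only chlorophyll-binding proteins, Rubisco small subunits, Rubisco activases and plastocyanins. Photosystem II 10 kDa polypeptide (TR11736|c0_g1), called for the average (log2 4.66), is not in it.

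**Figure D2:**
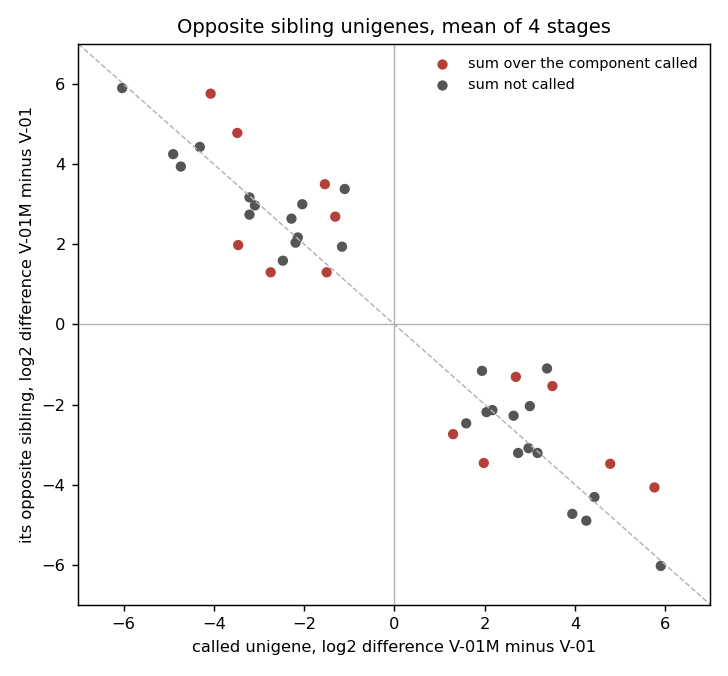
Log2 difference (V-01M minus V-01, averaged over 4 stages) of each called unigene against that of its sibling that went the other way, in red where the summed component was called and in grey where it was not. Of 41 such unigenes in 20 components, 6 components were called when summed, and the median size of the difference went from 2.97 to 0.79.

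At stage I a non-specific lipid-transfer protein (TR10166|c0_g1) stood at 428 ± 250 FPKM in V-01 and 25.3 ± 43.1 FPKM in V-01M (log2 −6.17, SE 1.25, adjusted p = 0.0345). Cysteine proteinase 3 (TR8573|c0_g1) was at 44.1 ± 17.8 and 4.8 ± 8.31 FPKM (log2 −4.11, SE 0.84, adjusted p = 0.0376), and transcription factor MYB21 (TR23843|c0_g1) at 8.12 ± 1.65 and 1.27 ± 1.45 FPKM (log2 −2.20, SE 0.46, adjusted p = 0.0393). These 3 calls ended without any of V-01_I-1 (−6.07, −4.16 and −2.12), V-01_I-2 (−6.69, −4.36 and −2.12), V-01_I-3 (−5.73, −3.81 and −2.36), V-01M_I-2 (−4.98, −3.45 and −1.71) or V-01M_I-3 (−5.42, −3.45 and −2.20). They also ended with a pseudocount of 0.1 (−7.60, −6.32 and −3.58), and the MYB21 call with replicates 2 and 3 only (−2.61) and with a replicate term. A GDSL esterase or lipase (TR15892|c0_g2) was lower in V-01M by log2 −2.56 (SE 0.39, adjusted p = 0.00273). With only the groups compared in the fit all 4 calls ended, at adjusted p values of 0.927, 0.936 and 0.754 for the 3 and 0.358 for the esterase.

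Stage I held 144 called unigenes (40 higher, 104 lower in V-01M), and 174 (48 and 126) with replicates 2 and 3 only. The count was 94 without V-01_I-1, 82 without V-01_I-3, 353 without V-01M_I-1 and 75 without V-01M_I-2. Specialised metabolism had 1 unigene that rose, cell wall 1 that rose and 2 that fell, transcription factors 1 that fell, cleavage and storage 2 that fell and stress 1 that fell. Photosynthesis, isoprenoid, phenylpropanoid, proliferation, carotenoid and other-tissue unigenes had 0 calls, with 3, 3, 3, 0, 0 and 1 at an unadjusted p under 0.05 in limma. Over the list alone 3 photosynthesis unigenes rose, 2 stress unigenes rose and 1 fell, and 3 cleavage and storage unigenes fell, with 2 and 1 in specialised metabolism, 2 and 2 in the cell wall list and 0 transcription factors.

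At stage II 47 of the called unigenes were ones called in the same direction at all 4 stages, such as TR16972|c0_g2 (31.8 ± 4 FPKM in V-01M, 0.153 in V-01) and TR29833|c0_g2 (log2 2.23, SE 0.24). Stage II held 71 called unigenes (34 higher, 37 lower), and 47 (28 and 19) with replicates 2 and 3 only. Cell wall unigenes had 2 that rose and 2 that fell (2 and 4 over the list alone), specialised metabolism 1 that rose, and the other 9 lists 0 calls. Among those 9, limma gave an unadjusted p under 0.05 to 14 transcription factors, 9 cleavage and storage unigenes, 4 phenylpropanoids, 1 each of the isoprenoid, proliferation and other-tissue unigenes, and 0 of the carotenoid, photosynthesis and stress unigenes.

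At stage III a pair of enzyme unigenes known from anthers was higher in V-01M than in V-01. Cytochrome P450 CYP703A2 (TR10129|c0_g1), an enzyme for precursors of the pollen wall polymer sporopollenin, stood at 11.1 ± 0.954 FPKM in V-01M and 0.343 ± 0.315 FPKM in V-01 (log2 3.20, SE 0.62, adjusted p = 0.0243), and 4-coumarate CoA ligase-like 1 (TR6055|c0_g1) at 7.58 ± 5.39 and 0.208 ± 0.25 FPKM (log2 2.62, SE 0.44, adjusted p = 0.00595). MADS-box factor AGL15 (TR3265|c0_g1) stood at 34 ± 23.2 and 3.96 ± 6.29 FPKM (log2 3.31, SE 0.67, adjusted p = 0.0346), and GDSL esterase 1 (TR29078|c0_g1) at 15 ± 3.4 and 3.86 ± 2.89 FPKM (log2 1.86, SE 0.30). The CYP703A2 and AGL15 calls ended after quantile normalization (2.99 and 3.05) and without V-01_III-2 (3.25 and 2.83), V-01_III-3 (3 and 2.72), V-01M_III-1 (3.14 and 2.82) or V-01M_III-3 (3.19 and 3.02). They also ended with fabavirus load as a covariate (2.96 and 3.33, adjusted p = 0.0645 each). With replicates 2 and 3 only CYP703A2 was at 3.29 and not called, and with a pseudocount of 5 CYP703A2 (1.59), AGL15 (2.09) and TR6055|c0_g1 (1.18) were not called. With only the groups compared in the fit CYP703A2 stayed called, and TR6055|c0_g1 (adjusted p = 0.4), AGL15 (adjusted p = 0.709) and TR29078|c0_g1 (adjusted p = 0.489) did not.

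Stage III held 140 called unigenes (94 higher, 46 lower, 1 of them viral), and 130 (93 and 37) with replicates 2 and 3 only. The count was 628 without V-01_III-1, 93 without V-01_III-3 and 463 without V-01M_III-2. Specialised metabolism had 2 that rose, transcription factors 1, phenylpropanoids 1 and cleavage and storage 1, while 1 cell wall unigene rose and 3 fell. Over the list alone 3 specialised metabolism unigenes rose, 3 transcription factors rose and 1 fell, 2 cleavage and storage unigenes rose and 5 fell, 2 cell wall unigenes rose and 3 fell, 1 phenylpropanoid unigene rose and 1 photosynthesis unigene fell. Photosynthesis, isoprenoid, proliferation, stress and other-tissue unigenes had 0 calls, with 7, 1, 4, 9 and 1 at an unadjusted p under 0.05 in limma.

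At stage IV cellulose synthase-like E1 (TR3297|c0_g1) stood at 14 ± 0.855 FPKM in V-01M and 0.397 ± 0.688 FPKM in V-01 (log2 3.52, SE 0.65, adjusted p = 0.01), and cytochrome P450 CYP82C4 (TR28536|c0_g1) at 20.7 ± 4.27 and 1.4 ± 1.12 FPKM (log2 3.27, SE 0.64, adjusted p = 0.0167). GDSL esterases TR3517|c0_g1 (19.5 ± 5.04 against 2.89 ± 1.92 FPKM) and TR18615|c0_g1 (18.8 ± 9.83 against 3.67 ± 2.19 FPKM) were higher in V-01M, with log2 differences of 2.50 (SE 0.33) and 2.12 (SE 0.43). A cysteine proteinase inhibitor (TR12617|c0_g1) was lower, at 4.32 ± 3.09 against 59.3 ± 56.2 FPKM (log2 −3.10, SE 0.59, adjusted p = 0.0122). With replicates 2 and 3 only TR3517|c0_g1 stayed called, and TR3297|c0_g1 (3.87), TR28536|c0_g1 (3.61), TR18615|c0_g1 (2.02) and TR12617|c0_g1 (−2.10) did not. With only the groups compared in the fit none of the 5 stayed called, TR3517|c0_g1 included (adjusted p = 0.19, the others 0.0701 to 0.407). The 4 calls lost with replicates 2 and 3 also ended without V-01M_IV-1 (3.49, 3.27, 1.74 and −2.88), TR28536|c0_g1 without V-01_IV-3 (2.92) or V-01M_IV-2 (3.13) and with a pseudocount of 0.1 (4.10), and TR18615|c0_g1 without V-01_IV-2 (1.64) and with a pseudocount of 5 (1.42). Unmatched unigene TR831|c0_g1 read 4480, 263 and 2120 FPKM in the libraries of V-01 and 19.9 ± 22.8 FPKM in V-01M, a call that ended with replicates 2 and 3 only (−4.91) and with only the groups compared in the fit (adjusted p = 0.268). Other calls were also larger than that of TR3297|c0_g1. With only the groups compared these were at 13.85 (TR27130|c16_g1), 12.33 (TR12235|c0_g1), 11.46 (TR26491|c6_g3), −7.02 (TR11979|c0_g1) and −6.62 (TR9365|c0_g1). They ended in that fit (adjusted p = 0.111 to 0.409) and with replicates 2 and 3 only.

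Stage IV held 337 called unigenes (204 higher, 133 lower, 7 of them viral), and 102 (68 and 34) with replicates 2 and 3 only. The count was 134 without V-01M_IV-1 and 213 without V-01M_IV-2. The median of all unigenes lay at 0.102 in log2 units and moved to 0.021 after median-of-ratios scaling and −0.049 after quantile normalization. Cell wall unigenes had 6 that rose and 2 that fell (14 and 4 over the list alone), cleavage and storage 2 that rose (9 over the list alone), specialised metabolism 2 that rose and 3 that fell, transcription factors and other tissues 1 each that rose, and stress 1 that fell. Photosynthesis, phenylpropanoid, isoprenoid and proliferation unigenes had 0 calls, with 19, 4, 4 and 2 at an unadjusted p under 0.05 in limma, and 4 photosynthesis unigenes rose over the list alone. Over the list alone specialised metabolism also had 3 that rose and 4 that fell, other tissues 3 and 2, phenylpropanoids 1 and 0, stress 0 and 1, and transcription factors 0.

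**Figure D3:**
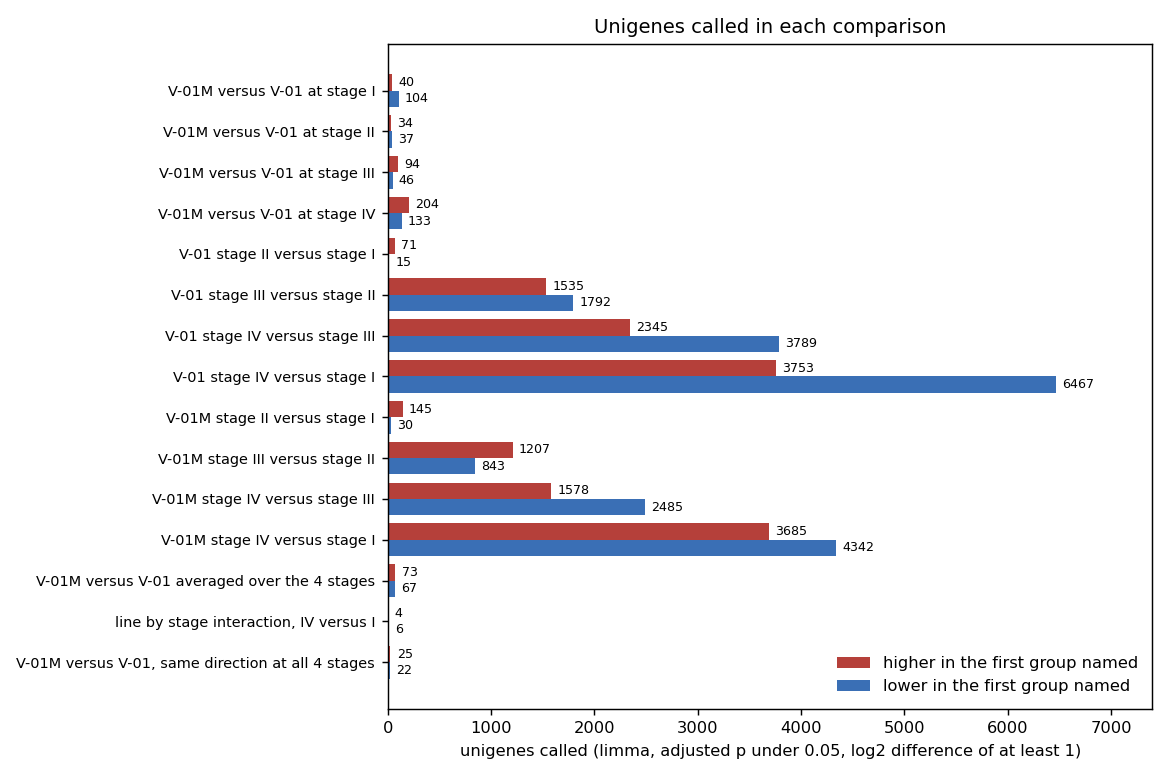
Number of unigenes called higher or lower in each comparison (adjusted p under 0.05 and a log2 difference of at least 1; n = 3 libraries per group). Line comparisons at single stages held 71 to 337 calls and stage IV against stage I 10220 in V-01 and 8027 in V-01M.

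Cell division transcripts fell in both lines as the petals developed. Of 16 histone H4 unigenes 16 fell from stage I to IV in each line, as did all 7 replication helicase (MCM) unigenes and all 3 B-type cyclin-dependent kinases. Histone H2A variant 1 (TR18956|c0_g1) went from 55.3 ± 30.7 to 2.07 ± 2.17 FPKM in V-01 (log2 −4.28), and histone H2B.3 (TR27931|c1_g1) from 1090 ± 261 to 27 ± 19.2 FPKM in V-01M (log2 −5.69). Of 112 proliferation unigenes 98 fell and 1 rose in V-01, and 101 fell and 0 rose in V-01M, with median log2 changes of −2.21 and −2.99. The list was called down by camera in V-01 (adjusted p = 1.18e-17, and adjusted p = 0.681 with an estimated correlation) and in V-01M (adjusted p = 5.59e-37, and adjusted p = 0.681 with an estimated correlation).

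Several regulators and enzymes of late petals rose from near 0. Transcription factor MYB21 (TR27296|c0_g14), a regulator of late petal and stamen growth, reached 114 ± 43.5 FPKM in V-01 (log2 6.67, SE 0.61) and 102 ± 11.3 FPKM in V-01M (log2 6.08). Myb-related protein 305 (TR319|c0_g1) was listed at 0 at stage I of V-01 and reached 67.2 ± 28.5 FPKM, and 47.2 ± 13.7 FPKM in V-01M. Cytochrome P450 CYP76C4 (TR7817|c0_g1) rose from 0.0413 to 132 ± 85.3 FPKM in V-01 (log2 6.68, SE 0.41) and from 0.158 to 51.9 ± 22.2 FPKM in V-01M (log2 5.46). NAC factor 56 (TR12452|c0_g3) rose from 0.393 to 70.9 ± 16.2 FPKM in V-01 (log2 5.67, SE 0.26), and xyloglucan endotransglucosylase 6 (TR16902|c0_g1), which remodels cell walls, from 0.406 to 43.6 ± 19 FPKM in V-01 and from 0.478 to 46 ± 17.5 FPKM in V-01M (log2 4.89 and 5.01). Geranylgeranyl diphosphate synthase unigenes, whose product feeds carotenoid synthesis, rose as well, TR30864|c1_g1 from 0.0891 to 9.57 ± 4.56 FPKM in V-01 and TR30864|c0_g1 from 0.0323 to 18.2 ± 6.76 FPKM in V-01M.

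Some transcripts known from young anthers fell over the same course. Ligase-like 1 (TR6055|c0_g1) fell from 106 ± 43.5 to 0.0619 FPKM in V-01 (log2 −6.59, SE 0.44) and from 91 ± 37.5 to 0.109 FPKM in V-01M (log2 −6.29), and cytochrome P450 CYP704B1 (TR5272|c0_g1) from 95.1 ± 27.9 to 0.029 FPKM in V-01 (log2 −6.51, SE 0.74). Another CYP704B1 unigene, TR24547|c0_g1, chosen after its values were seen, went the other way, from 2.49 ± 1.19 to 12.8 ± 4.02 FPKM in V-01 and from 2.4 ± 0.9 to 10.8 ± 1.24 FPKM in V-01M. Dihydroflavonol reductase (TR9358|c0_g1) fell in both lines (log2 −3.85 and −3.59), while chalcone synthase 3 (TR3036|c0_g1), for the first step of flavonoid synthesis, rose to 38.3 ± 42.1 FPKM in V-01 (log2 4.25, SE 0.85) and chalcone synthase TR4580|c0_g1 fell from 452 ± 91.1 to 126 ± 32.8 FPKM in V-01M (log2 −1.85). Light-harvesting protein P4 (TR20760|c0_g1) fell from 63.5 ± 10.7 to 10.6 ± 4.44 FPKM in V-01 (log2 −2.53). Rubisco small subunit TR29729|c0_g1 fell from 59.6 ± 26 to 12.4 ± 6.32 FPKM in V-01 (log2 −2.21), a call that ended without V-01_I-3 (−1.95) or V-01_IV-1 (−1.72) and with fabavirus load as a covariate (−2.06). In V-01M the Rubisco unigene TR26797|c0_g1 read 226, 133 and 0 FPKM in V-01M_I-1, V-01M_I-2 and V-01M_I-3, and its fall was not called with replicates 2 and 3 only (−3.53) or with only the groups compared in the fit (adjusted p = 0.133).

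From stage I to IV 10220 unigenes were called in V-01 (3753 up, 6467 down) and 8027 in V-01M (3685 up, 4342 down), and 8391 (2911 and 5480) and 5570 (2249 and 3321) with replicates 2 and 3 only. Of these 2389 rose and 3466 fell in both lines, where independent lists of these sizes would share 326 and 662, and 10 went opposite ways. The median of all unigenes in V-01 lay at −0.201 in log2 units and moved to −0.168 after median-of-ratios scaling and 0.009 after quantile normalization. Carotenoid unigenes had 3 that rose and 0 that fell of 13 in V-01 and 4 and 0 in V-01M (5 and 0 over the list alone). Isoprenoid unigenes had 10 and 11 of 43 in V-01 and 10 and 9 in V-01M, phenylpropanoids 15 and 3 of 43 and 6 and 3, photosynthesis 0 and 20 of 58 and 3 and 4, and cell wall 40 and 52 of 226 and 55 and 32. Transcription factors had 92 and 88 of 517 and 84 and 78, stress 7 and 4 of 69 and 13 and 4, specialised metabolism 80 and 47 of 314 and 71 and 37, cleavage and storage 17 and 41 of 110 and 15 and 30 (15 and 41 and 14 and 30 of these GDSL esterases or lipases, 2 and 0 and 1 and 0 dioxygenases), and other tissues 2 and 3 of 20 and 1 and 1. Over the lists alone these counts moved by at most 4.

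In V-01 camera called 4 of 9 lists from stage I to IV, proliferation included. Specialised metabolism was up (adjusted p = 0.000583, and adjusted p = 0.681 with an estimated correlation), with a median log2 change of 0.22, as were phenylpropanoids (adjusted p = 0.0059, and adjusted p = 0.681 with an estimated correlation) at 0.49. Photosynthesis was down (adjusted p = 0.00637, and adjusted p = 0.712 with an estimated correlation) at −0.91, and not called without V-01_I-2 (0.0543) or V-01_IV-1 (0.191). Carotenoid (0.0794), transcription factor (0.0794), stress (0.186), isoprenoid (0.523) and cell wall unigenes (0.779, tested up with a median of −0.10) were not called. Carotenoids were called without V-01_I-2 (0.0339) or V-01_IV-1 (0.0294), and transcription factors without V-01_I-2 (0.0172).

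In V-01M camera called carotenoids up (adjusted p = 0.00232, and adjusted p = 0.681 with an estimated correlation) with a median log2 change of 0.70, specialised metabolism up (adjusted p = 0.00311, and adjusted p = 0.681 with an estimated correlation) at 0.32, and stress and senescence up (adjusted p = 0.0187, and adjusted p = 0.681 with an estimated correlation) at 0.38. The stress call ended without V-01M_IV-3 (0.0842), and phenylpropanoids (0.0988) were called without V-01M_IV-1 (0.0397). Cell wall (0.0935), photosynthesis (0.617), isoprenoid (0.622) and transcription factor unigenes (0.851) were not called.

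Between the lines, averaged over stages, camera called carotenoids down in V-01M (adjusted p = 0.00464, and adjusted p = 0.681 with an estimated correlation) at a median of −0.15. No member was called, and the values ran from −0.58 (TR3323|c0_g1, adjusted p = 0.738) to 0.20 (TR9258|c0_g1, adjusted p = 0.791). It called proliferation up (adjusted p = 3.49e-05, and adjusted p = 0.712 with an estimated correlation) at a median of 0.29. The carotenoid call ended without V-01_III-3 (0.0654) and the proliferation call without V-01_I-2 (0.111). The other 7 lists had adjusted p from 0.273 to 0.987, and photosynthesis was called without V-01_III-1 (0.0154) or V-01_IV-1 (0.0235).

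The successive steps showed when the groups moved. From stage II to III cell wall unigenes had 44 that rose and 16 that fell in V-01 and 23 and 7 in V-01M, and from stage III to IV 13 and 67 in V-01 and 20 and 31 in V-01M. Proliferation unigenes had 17 that fell from stage II to III and 4 from III to IV in V-01, and 6 and 51 in V-01M. Over the list alone 42 and 3 fell in V-01 and 34 and 66 in V-01M, and the median log2 changes from stage II to III were alike (−1.26 in V-01, −1.22 in V-01M), with −0.76 and −1.51 from III to IV. Carotenoids had 5 that rose and then 4 that fell in V-01, and 0 and 1 that rose in V-01M. From stage II to III 5 rose in V-01 and 1 in V-01M over the list alone, with median log2 changes of 0.97 and 0.3. The stage III libraries of V-01 differed widely for the 5, and the carotenoid count with a library left out is not given. Isoprenoid unigenes had 6 that rose and 0 that fell from stage II to III in V-01 and 3 and 0 in V-01M, and specialised metabolism had 57 and 34 from stage III to IV in V-01 and 75 and 22 in V-01M. The steps II to I, III to II and IV to III called 86, 3327 and 6134 unigenes in V-01 and 175, 2050 and 4063 in V-01M, and 4, 2627 and 4664 and 185, 458 and 2210 with replicates 2 and 3 only.

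Single libraries moved several of these step counts. In V-01 the step to stage II called 7 unigenes without V-01_I-1, 20 without V-01_I-2 and 14 without V-01_II-1, and the step to stage III 2076 without V-01_III-3. In V-01M the step to stage II called 680 without V-01M_I-1, 35 without V-01M_I-2, 115 without V-01M_I-3, 45 without V-01M_II-2 and 23 without V-01M_II-3. The V-01M step to stage III called 1130 without V-01M_II-1, 1208 without V-01M_II-2 and 1116 without V-01M_III-1, and the step to stage IV 2337 without V-01M_IV-3.

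Few unigenes were called for a difference between the lines in the change from stage I to IV, and draws of the line labels often called as many (24 of 100 draws). Glycine-rich cell wall protein 1 (TR17875|c0_g1) fell from 48.7 to 1.44 FPKM in V-01 and from 32.4 to 17.6 FPKM in V-01M (interaction log2 3.56, SE 0.57, adjusted p = 0.0332). A BURP-domain protein (TR31231|c0_g1) went from 0.475 to 29.9 FPKM in V-01 and was listed at 0 at both stages of V-01M (adjusted p = 0.00681). Unmatched unigene TR25857|c0_g1 went from 69.7 to 0.369 FPKM in V-01 and from 3.68 to 0.905 FPKM in V-01M (interaction log2 4.82, SE 0.72). In all 10 unigenes were called (4 with a higher, 6 with a lower change in V-01M, the 6 at no more than 0.549 FPKM on average at stages I and IV except at stage IV of V-01), and 52 (44 and 8) with replicates 2 and 3 only. No list member was called in limma, and over the lists alone 4 cell wall unigenes, 2 cleavage and storage unigenes and 1 photosynthesis unigene had a higher change. Stress had 1 higher and 3 lower and other tissues 3 and 1. The median of all unigenes lay at 0.124 in log2 units and moved to 0.030 after median-of-ratios scaling and −0.030 after quantile normalization.

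The interaction count was 4 without V-01_I-1 or V-01_I-3, 32 without V-01_IV-1, 150 without V-01_IV-2, 16 without V-01_IV-3, 172 without V-01M_I-1, 63 without V-01M_I-3, 5 without V-01M_IV-1, 6 without V-01M_IV-2 and 33 without V-01M_IV-3. Camera called 6 lists. Proliferation had a lower change in V-01M (adjusted p = 2.04e-13, and adjusted p = 0.681 with an estimated correlation; median −0.83), as did transcription factors (adjusted p = 0.00695, and adjusted p = 0.681 with an estimated correlation; median −0.07) and phenylpropanoids (adjusted p = 0.0479, and adjusted p = 0.712 with an estimated correlation; median −0.03). Photosynthesis (adjusted p = 0.000159, and adjusted p = 0.712 with an estimated correlation), cell wall (adjusted p = 0.00678, and adjusted p = 0.681 with an estimated correlation) and carotenoids (adjusted p = 0.0496, and adjusted p = 0.712 with an estimated correlation) had a higher one, with medians of 0.79, 0.36 and 0.35. The carotenoid call ended without V-01_I-2 (0.425), V-01_IV-1 (0.327), V-01_IV-3 (0.0539), V-01M_I-1 (0.145), V-01M_I-3 (0.12) or V-01M_IV-1 (0.164), and the photosynthesis call without V-01_IV-1 (0.18) or V-01M_I-3 (0.0627). The cell wall call ended without V-01_I-3 (0.0558) or V-01_IV-2 (0.055), and the transcription factor call without V-01_I-1 (0.0632), V-01_I-3 (0.0643), V-01_IV-3 (0.0542) or V-01M_I-2 (0.127). The phenylpropanoid call ended without V-01_I-1 (0.182), V-01_I-3 (0.203), V-01_IV-2 (0.0929), V-01_IV-3 (0.0705), V-01M_I-2 (0.186), V-01M_I-3 (0.12) or V-01M_IV-1 (0.218). Stress (0.196), specialised metabolism (0.289) and isoprenoid unigenes (0.622) were not called, though specialised metabolism was without V-01M_I-1 (0.0279) and stress without V-01M_IV-1 (0.0401).

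Unigenes matched to fabaviruses held a part of the values in every library. These 117 unigenes, matched to polyproteins of RNA1 and RNA2, took 11.2% (V-01_I-3) to 71.0% (V-01M_III-1) of the sum of FPKM times length, with a median of 39.8%, and 10 libraries were over 50%. Whether they came from 1 virus was not tested. Group means at stages I to IV were 18.5%, 43.6%, 47.8% and 48.7% in V-01 and 24.7%, 30.3%, 64.7% and 49.8% in V-01M. In V-01 stage I lay under the later stages (exact permutation p = 0.00455, 220 groupings), and in V-01M the same test gave an exact permutation p = 0.132. This test of stages was chosen after the virus share was seen. The plant part of the sum varied by a factor of 1.28 between libraries.

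**Figure D4:**
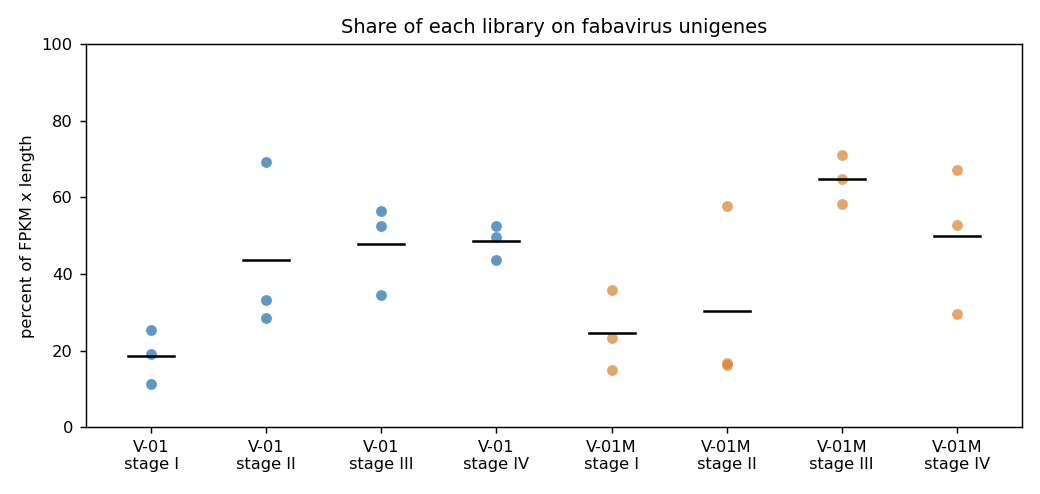
Percent of the sum of FPKM times length that fell on fabavirus unigenes in each library (points), by line and stage, with the group mean as a line (n = 3). Group means ran from 18.5% at stage I of V-01 to 64.7% at stage III of V-01M.

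A few libraries also stood out for groups of unigenes. V-01_IV-1 held seed storage 2S proteins at up to 7500 FPKM, 11S globulins at up to 1640 FPKM and oleosins at up to 486 FPKM (1 oleosin, TR7398|c0_g1, also reached 171 FPKM outside stage IV of V-01), and oleosin 1 (TR19838|c0_g1) read 404, 0.707 and 5.69 FPKM in V-01_IV-1, V-01_IV-2 and V-01_IV-3. Its call from stage I to IV in V-01 (log2 3.58, SE 1.14) ended with replicates 2 and 3 only (1.07), without V-01_I-1 (3.38) or V-01_I-3 (3.39), with only the groups compared in the fit (adjusted p = 0.236) and with fabavirus load as a covariate (3.82). Of 27 unigenes seen at stage I of V-01M and in no other group, 26 reached 5 FPKM in V-01M_I-1, 23 in V-01M_I-2 and 1 in V-01M_I-3, and 17 of the 27 matched chloroplast proteins, and their origin was not tested.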

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

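The tests of opposite siblings against matched draws, of fabavirus as a covariate, of dilution and carry-over, of the summed components and of a wrongly labelled library were chosen only after the results were seen.

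Line differences averaged over the 4 stages often came as pairs of siblings that went opposite ways. Of 138 plant unigenes called, 41 had a sibling that went the other way, against at most 6 in 10000 matched draws, and in 39 of them at least 100 bases aligned, at a median identity of 98.9%. The 41 made up 21 distinct pairs, most of them counted from both sides, which the draws would seldom do. Summed over components, 6 of the 20 were called, and the median size of the difference went from 2.97 to 0.79, so a candidate explanation is that reads of 1 gene were split between near-identical unigenes by sequence differences between the lines. Of the 97 called unigenes without such a sibling, 3 had an opposite match in another component (at most 1 in each of 20 sets of matched draws). The other 94 (50 higher, 44 lower) had no partner by these limits. Some of the 94 had siblings and were not called when summed, such as TR26791|c4_g4 (log2 4.06, sum 0.15) and TR26694|c0_g4 (3.97, sum 0.33), so reads shared among siblings stay open for them. Others stayed called when summed, such as TR14192|c0_g2 (3.75, sum 4.35). For these, absence of a gene or a change in its level both stay open. Fabavirus load is unlikely to account for the calls, since 135 of the 140 stayed called in the same direction with it as a covariate (137 calls in all), and their median size went from 2.09 to 2.12.

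The fabavirus share of the libraries ran from 11.2% to 71.0%. Dilution of plant values by viral reads would spread the plant sum as the non-viral shares spread, by 3.06, and it spread by 1.28, which points against dilution in the deposited values. Carry-over from a few infected libraries is unlikely with a lowest share of 11.2%. A difference between the lines could not be told from chance (exact permutation p = 0.719 over 160000 labellings, mean difference 0.15 in log2 units, higher in V-01M at 3 of 4 stages), and at stage III the exact permutation p = 0.1 was the smallest that 3 libraries against 3 can give. Within groups limma found 0 of 42308 plant unigenes to follow the load, and 826 at an unadjusted p under 0.05.

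Unigenes seen at stage IV of V-01 and in no other group numbered 86, taking at least 5 FPKM in the group and under 0.5 FPKM in all other libraries. A test set down beforehand was whether seed markers not yet looked at would be highest there: 25 of 41 (61.0%) were, 22 of them in V-01_IV-1, and 18 were over 10 times the level of the other 21 libraries. This points to seed or embryo tissue in V-01_IV-1. The 41 markers are not among the 86, since each reached 0.533 FPKM or more in another group, so the test does not show where the 86 came from. Several were siblings of TR28064|c0_g3, a marker already seen, and are not independent of it. Seed tissue in V-01_IV-1 does not account for 46 of the 86, which were at 0 in V-01_IV-1 and reached 5 FPKM in replicate 2 or 3 (a test chosen after these values were seen). A single wrongly labelled library would not account for all of the 86, since 40, 46 and 69 of them reached 5 FPKM in replicates 1, 2 and 3. Whether it accounts for a part could not be told, because the 86 are pooled over the 3 libraries. Part of the 86 (8) matched Cucumis proteins and 25 had no match, and where they came from stays open.

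Splits of 6 libraries into 3 and 3 are too few for a share under 0.05, so they are given as real and highest other counts alone. At stages I to IV of the line comparison the real counts were 144, 71, 140 and 337 and the highest others 1033, 2, 778 and 12. The stage I split that called 1033 set V-01_I-1, V-01_I-3 and V-01M_I-1 against the rest, as they lie on the principal component plot, and the stage III split that called 778 set V-01_III-1, V-01M_III-1 and V-01M_III-3 against the rest: both point to a structure of the samples that does not follow the lines. In V-01 the steps to stages II, III and IV called 86, 3327 and 6134 against 4, 2 and 9, and stage IV against I 10220 against 1427. In V-01M the steps called 175, 2050 and 4063 against 1, 0 and 5, and stage IV against I 8027 against 4. For lists, 4 were called in V-01 and 4 in V-01M and up to 6 in another split, and 5 of the 10 splits in each line called as many.

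The 100 draws of the line labels within stages count the real labelling as 1 of them, so they cannot exclude chance. By these draws chance was made unlikely for the averaged line difference (140 called, highest other draw 108) and for calls in 1 direction at all 4 stages (47, highest other 0). It was not made unlikely for the lists of the averaged difference (2 called, up to 8 in other draws, and as many in 79 draws). Nor was it made unlikely for the interaction (10 called, up to 543, as many in 24 draws) or for its lists (6 called, up to 8, as many in 11 draws).

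The interaction of line with stage IV against stage I called 10 unigenes. Camera called its carotenoid list at an adjusted p = 0.0496, proliferation at an adjusted p = 2.04e-13, cell wall at an adjusted p = 0.00678, phenylpropanoids at an adjusted p = 0.0479, photosynthesis at an adjusted p = 0.000159 and transcription factors at an adjusted p = 0.00695. None of the 6 stayed called with an estimated correlation (0.681 or 0.712) or with fry (0.084 to 0.783). Cucumovirus unigenes took up to 0.03064% of FPKM times length, in V-01_II-3.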

How the results depend on the processing

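Settings named as added (replicates 2 and 3 only, fabavirus load as a covariate, sums over siblings, fits without virus or 1-group unigenes) were chosen only after the result was seen.

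Counts given in the report moved with the floor, the libraries and the groups in the fit, and list calls moved with the correlation assumed between genes, and unless said otherwise the cause was not tested. Among 2704 alternative values for named unigenes in comparisons where they were called, 2567 (94.9%) kept the call and 137 lost it, and among 1139 where they were not called 9 gained a call, and 0 were reversed. These values cover the line comparisons and stage IV against stage I, with 138 calls, and not the unigenes named for successive steps. With a pseudocount of 0.1 the line comparison called 238 at stage III and 682 at stage IV, the step to stage II 46 in V-01 and 94 in V-01M, and the interaction 63, and its carotenoid and phenylpropanoid lists were at adjusted p values of 0.0816 and 0.0694. With a pseudocount of 5, which shrinks differences at low levels by construction, the counts were 80 and 202 at stages III and IV, 66 for the average, 29 at all 4 stages, 18 for the interaction (phenylpropanoids 0.0615), 1859, 3437 and 5197 for III against II, IV against III and IV against I in V-01 and 1151, 2217 and 4264 in V-01M. Without a filter the V-01 step to stage II called 57, and in the interaction phenylpropanoids were at 0.0569 and photosynthesis at 0.429. With a mean of at least 5 FPKM, which leaves fewer unigenes, the line comparison called 70, 39 and 77 at stages I to III, 65 on average and 29 at all 4 stages, the interaction 0, the steps in V-01 21, 1890 and 4068 with 5944 for IV against I, and in V-01M 89 and 1276 with 4740; lists moved to 0.0506 (carotenoids, interaction), 0.0894 (phenylpropanoids, V-01) and 0.0321 (cell wall, V-01M, called). With other scaling, median-of-ratios gave 0.0752 for carotenoids in the interaction, and quantile normalization 189 for the V-01 step to stage II, 0.153 for phenylpropanoids and 0.0229 for stress in the interaction, and 0.0542 for stress in V-01M. A replicate term gave 151 for that step and 0.0508 for carotenoids and for phenylpropanoids in the interaction. At an adjusted p under 0.01 the counts were 85, 82 and 133 at stages I, III and IV, 9, 1766 and 4030 for the steps in V-01, 47, 913 and 2025 in V-01M, and 3 for the interaction. An estimated correlation put all list calls at 0.681 or 0.712, and fry, another kind of test, kept proliferation (0.00271) and specialised metabolism (0.00851) in V-01 and the 4 calls in V-01M (0.000282 to 0.0121), and put the others at 0.396 (carotenoids), 0.519 (proliferation), 0.084 (cell wall), 0.783 (phenylpropanoids and transcription factors) and 0.362 (photosynthesis) in the interaction, 0.185 (phenylpropanoids) and 0.0945 (photosynthesis) in V-01, and 0.519 (carotenoids) and 0.465 (proliferation) for the average. With only the groups compared in the fit the counts were 41, 52 and 36 at stages I, III and IV, 11 at all 4 stages, 5 for the interaction, 4, 1320 and 3553 for the steps in V-01 and 39 for the V-01M step to stage II, and transcription factors in V-01 were called (0.0462). With replicates 2 and 3 only they were 47 and 102 at stages II and IV, 27 at all 4 stages, 52 for the interaction, 4 for the V-01 step to stage II and 458 and 2210 for the later V-01M steps; in the interaction carotenoids (0.318), cell wall (0.167), phenylpropanoids (0.123) and photosynthesis (0.0864) lost their call and specialised metabolism (0.0302) and stress (0.0193) gained one, and for the average cell wall (0.0262) and photosynthesis (0.000588) gained one. With fabavirus load as a covariate the V-01 step to stage II called 1 and the V-01M step to stage III 873, though the median size of the changes called before went only from 2.54 to 2.49 and from 1.74 to 1.71, and carotenoids (0.0553, interaction) and stress (0.0509, V-01M) lost their call. Summed over siblings the line comparison called 75, 22 and 79 components at stages I to III, 77 on average and 12 at all 4 stages. Leaving out each library in turn gave 75 to 353, 93 to 628 and 134 to 400 for the line at stages I, III and IV, 126 to 224 for the average, 4 to 172 for the interaction, 7 to 114 and 2076 to 4191 for the first steps in V-01 and 23 to 680, 1116 to 1990 and 2337 to 3769 for those in V-01M. For lists it gave 0.0294 to 0.202 (carotenoids), 9.24e-05 to 0.191 (photosynthesis) and 0.0172 to 0.203 (transcription factors) in V-01, 0.0397 to 0.314 (phenylpropanoids) and 0.00713 to 0.0842 (stress) in V-01M, and 5.16e-06 to 0.0654 (carotenoids), 1.86e-09 to 0.111 (proliferation) and 0.0154 to 0.95 (photosynthesis) for the average. In the interaction it gave 0.00961 to 0.425 (carotenoids), 0.000563 to 0.0558 (cell wall), 0.00509 to 0.218 (phenylpropanoids), 1.03e-08 to 0.18 (photosynthesis), 0.0279 to 0.807 (specialised metabolism), 0.0401 to 0.726 (stress) and 0.000427 to 0.127 (transcription factors).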

Other observations

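The pollen wall list was prompted by values already seen, its unigenes named here and those without a partner were picked only after their values were seen, and the only tests are limma calls.

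Petal samples of both lines carried transcripts known from the anther tapetum. Of 19 pollen wall unigenes 18 had a lower mean at stage III than at stage II in each line, and 16 had a higher mean in V-01M than in V-01 at stage III (12 of the 15 not looked at when the list was written). The means leaned the same way at stage II (16 higher in V-01M, 2 in V-01) and stage IV (14 and 4). Calls in limma at stage III were 2, both of unigenes that had prompted the list, and there were 0 at the other stages. Cytochrome P450 CYP703A2 (TR10129|c0_g1) averaged 62.5 ± 10.4, 34.7 ± 7.83, 0.343 ± 0.315 and 0.117 FPKM at stages I to IV of V-01 and 14.5 ± 14.8, 61 ± 9.68, 11.1 ± 0.954 and 0.357 FPKM in V-01M. Cytochrome P450 CYP704B1 (TR5272|c0_g1) averaged 0.101 FPKM at stage III of V-01 and 11 ± 2.09 FPKM in V-01M, fatty acyl reductase MS2 (TR28525|c0_g1) 0.865 and 19.6 ± 6.16 FPKM, and the tapetum regulator AMS (TR24419|c0_g1) 4.61 and 18.5 ± 10 FPKM. Going the other way at stage III were tetraketide reductase TKPR1 unigenes TR3386|c0_g1 (4.11 ± 2.15 FPKM in V-01, 1.52 ± 1.25 FPKM in V-01M) and TR27498|c1_g2 (1.13 and 0.931 FPKM) and TR1895|c0_g1 (0.162 and 0 FPKM). At stage I the means were mixed, 13 higher in V-01 and 6 in V-01M, with MS2 at 117 ± 16.9 FPKM in V-01 and 37.8 ± 59.5 FPKM in V-01M and TKPR1 TR5651|c0_g1 at 60.1 ± 18.5 and 92.5 ± 20.4 FPKM. In V-01M CYP703A2 read 30.2, 0.714 and 12.6 FPKM in V-01M_I-1, V-01M_I-2 and V-01M_I-3. Stages that are not matched in age between the lines and florets sampled with their anthers are candidate explanations that these data do not part, and the stage I split with 1033 calls, against 144 for the lines, points to a structure of the samples besides the lines.

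Among the 94 line differences without a partner were unigenes with known roles in development. EPIDERMAL PATTERNING FACTOR 2 (TR13190|c0_g1), a peptide that limits stomata, was higher in V-01M (log2 2.38), as were CONSTANS-LIKE 2 (TR24654|c0_g1, log2 2.19), plastid division factor MINE1 (TR18164|c0_g1, log2 1.49) and cellulose synthase-like E1 (TR3297|c0_g1, log2 1.89), and receptor kinase PXL2 (TR6060|c0_g1) was lower (log2 −1.71). Ribosomal protein L7a-1 (TR15062|c0_g1) was higher by log2 1.5 in the line where L7a-2 (TR11255|c0_g2) was listed at 0 at stages I to III. Summed over the component of L7a-2 the difference was log2 −1.43, against −7.25 for the unigene alone.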
